A study of Escherichia coli with 12 samples.

How the data were processed

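The data were RNA-seq expression values of Escherichia coli K-12 MG1655 and its Δcra derivative in 12 libraries. Per the labels, cells grew with air at 37 °C in M9 medium with 0.2% glucose, fructose or acetate to the middle of exponential growth, RNA was stabilized with RNAprotect, total RNA was purified with an RNeasy Plus Mini kit that removes genomic DNA and was measured on a NanoDrop, and libraries followed the usual Illumina procedure. The submitters' processing notes name Bowtie 1.0.0 and Cufflinks 1.3.0 without saying what each did; the genome build and the annotation are not given in the sources used here, nor is the strandedness of the libraries. The deposited table gives FPKM per gene and library. Nothing was aligned or counted anew.

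The table listed 4594 genes, of which 4462 matched a gene name by locus tag and 132 did not and kept their identifier. Of all genes, 164 were at 0 in every library. No 2 libraries were identical (0 pairs). Because FPKM of genes with few fragments is spaced in steps of 1 fragment, the depth of each library was read from the low values of genes of 400 to 4000 bases, with a tolerance of 0.1 fragment and up to 10 fragments; 93.9% to 98.9% of those values came out whole. It came to 6.11 and 4.11 M fragments (M, units of 1000000) in WT glucose, 9.19 and 9.87 in WT fructose, 9.79 and 20.29 in WT acetate, 8.79 and 9.55 in Δcra glucose, 7.31 and 8.08 in Δcra fructose, and 8.26 and 7.7 in Δcra acetate. A single fragment in a gene of 1000 bases was thus 0.064 to 0.333 FPKM. FPKM summed to 10.3 to 15.1 M per WT library and 8.23 to 10.2 M per Δcra library, and 337 to 409 genes were at 0 in a library. Log2 values of the 2 libraries of a group correlated at 0.927 to 0.956 over the genes tested, the median absolute log2 difference between them was 0.083 to 0.134 over genes of 300 bases or longer never at 0, and recovered fragments varied 2.05 to 21.33 times as much as counting alone gives (chi-square over degrees of freedom).

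Samples were grouped by genotype and carbon source into 6 groups of 2. Libraries were scaled by median of ratios (factors 0.916 to 1.123), and log2(scaled FPKM + 1) was tested with limma 3.58.1 in R 4.3.3 for genes with a mean of at least 5 FPKM, 3548 genes, of which 188 were at 0 in some library and 420 were under 300 bases. A model of 6 group means (6 residual degrees of freedom) with an intensity trend in the variance prior gave 5 main contrasts, which set Δcra against WT on each source and WT on fructose and on acetate against WT on glucose. It also gave 3 secondary contrasts, the 3 interactions and an F test over 2 interaction contrasts. An additive model of carbon source and genotype (8 residual degrees of freedom) gave the genotype effect over all sources. Adjusted p is Benjamini-Hochberg at 0.05. Tables and figures were made with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

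Camera (limma, preset correlation 0.01) set 27 partly overlapping gene lists (572 entries, all in the table) against the other genes tested. They were the fructose operon, targets that Cra represses, targets that Cra activates, sugar uptake and glycolysis, gluconeogenesis, glyoxylate shunt and acetate uptake, TCA cycle, pyruvate dehydrogenase with overflow and fermentation, pentose phosphate and Entner-Doudoroff, aerobic respiration and ATP synthase, ribosomal proteins, flagella and chemotaxis, RpoS general stress, acid resistance, carbon scavenging under CRP, fatty acid degradation, amino acid synthesis, methionine and sulphur, nucleotide synthesis, nitrogen limitation, phosphate starvation, iron uptake, heat shock, SOS response, curli and type 1 fimbriae, stable RNA, and genes beside cra. Members counted as higher or lower passed adjusted p over all genes tested, with counts adjusted over the list alone where they differ.

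For each main contrast the named genes were cra, the 10 largest increases and 10 largest decreases by log2 among genes past the threshold whose libraries did not overlap between the groups and whose higher group had a mean of at least 10 scaled FPKM, up to 4 members of each list with the largest absolute change, and all members of the lists of Cra targets. Since short genes filled the first part, the same rule was applied after the data were seen to genes of 300 bases or longer that no library lists at 0 (3049 genes). Not every gene so picked is printed. Groups, tests, lists, the naming rule and the first set of other settings below were fixed before the data were examined.

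The steps were tested on simulated data with 3548 genes. Of 100 genes changed by log2 1 on fructose 84% were recovered (median 0.979), and of 100 changed by log2 2, 90% (median 2.008); 0.209% of 3348 unchanged genes were called, and 0 in a contrast with no change. The additive model recovered 91% and 94%, the F test 71% and 87%. Camera called the 1 shifted list (39 genes, log2 0.5) and 0 of 26 others, with correlation untested.

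Other settings tried were a pseudocount of 0.1 or 5, no filter or a mean of at least 20 FPKM, values as deposited or quantile normalization, no variance trend, array quality weights, the replicate number as a block, only the libraries compared, an absolute log2 change of at least 1, each library left out in turn, camera with an estimated correlation, and fry. Added after the data were seen were genes of 300 bases or longer never listed at 0, and voom on the recovered fragments. Models for counts, foreseen in case the table held them, were not used here since it holds FPKM. Reads of near-identical rRNA copies cannot be assigned with certainty.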

Results

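RNA was sequenced from Escherichia coli K-12 MG1655 and from its Δcra derivative, which lacks the gene of Cra, a regulator of central carbon metabolism also known as FruR. Per the labels, cells grew at 37 °C with air in M9 minimal medium holding 0.2% glucose, fructose or acetate, and were taken in the middle of exponential growth. The 2 genotypes and 3 carbon sources made 6 groups of 2 libraries, 12 libraries in all. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values may measure technical spread only. The table lists FPKM for 4594 genes, of which 164 were at 0 in every library and 3548 passed the filter and were tested. The steps between low values put the depth at 4.11 to 20.29 M (units of 1000000) fragments per library, lowest in WT glucose (6.11 and 4.11 M) and highest in the second WT acetate library. Levels are scaled FPKM, as mean ± SD with n = 2 unless stated, and folds are on the log2(value + 1) scale, which understates the change of genes with low values.

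The 2 libraries of each group lay close together, with r of 0.992 to 0.996 over 3049 genes of 300 bases or longer that no library lists at 0. Between WT groups, r was 0.933 for fructose and glucose, 0.89 for acetate and glucose, and 0.957 for acetate and fructose. Between Δcra groups, r was 0.973 for fructose and glucose, 0.903 for acetate and glucose, and 0.906 for acetate and fructose. Within a carbon source the genotypes correlated at 0.972 on glucose, 0.886 on fructose and 0.91 on acetate. WT fructose was thus nearer to WT acetate than to WT glucose, while Δcra fructose was nearer to Δcra glucose. Genes under 200 bases held 82.6% to 91.2% of FPKM in WT libraries and 76.2% to 86.7% in Δcra libraries, with both Δcra libraries below both WT libraries on each source. Many of them were listed at 0 in one library beside high values in another, so genes listed at 0 are given with each library's value.

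The transcript of cra (b0080) itself was measured first, as a check of the genotype labels. It stood at 149 and 132 scaled FPKM in the WT glucose libraries, 205 and 182 on fructose and 247 and 281 on acetate, and was listed at 0 in all 6 Δcra libraries. Within WT, cra was higher on fructose than on glucose (log2 0.46, adjusted p = 0.00906) and higher on acetate than on glucose (log2 0.91, adjusted p = 0.000204). The fructose difference was lost with a pseudocount of 0.1 and without the first WT fructose library.

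**Figure D1:**
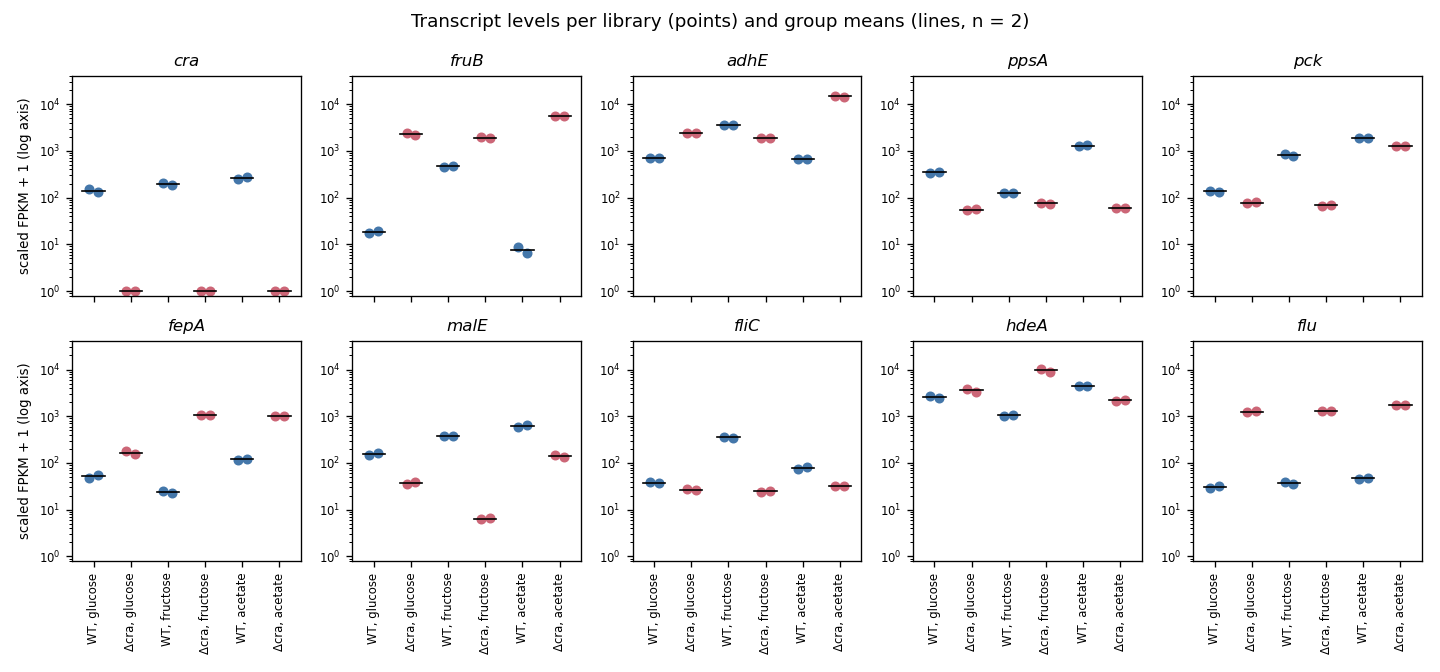
Scaled FPKM + 1 on a log axis for 10 genes, a panel each, in the 6 groups of genotype and carbon source, with points for libraries (blue WT, red Δcra) and lines for group means. cra lies at the floor in all Δcra libraries, fruB stands at 2340 in Δcra against 17.4 in WT on glucose, and fepA at 1062 against 23.0 on fructose.

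The comparison of Δcra with WT on glucose asks what the loss of Cra changes in cells fed the preferred sugar. The fructose operon rose most among long genes: fruB (b2169, the fructose-specific phosphoryl transfer protein, 2340 ± 158 vs 17.4 ± 1.25, 127-fold), fruA (b2167, the fructose permease, 2658 ± 107 vs 30.4 ± 3.15, 84.8-fold) and fruK (b2168, 1-phosphofructokinase, 1729 ± 91.3 vs 22.8 ± 0.0537, 72.5-fold), all given as Δcra against WT. All 3 members of this list were higher (median log2 6.41, camera adjusted p = 2.02e-06). Among the largest falls in long genes were ppsA (b1702, phosphoenolpyruvate synthase, 54.1 ± 1.24 vs 346 ± 7.19, 6.31-fold) and the maltose genes lamB (b4036, maltoporin, 13.8 ± 0.38 vs 77 ± 9.42, 5.26-fold) and malE (b4034, maltose-binding protein, 36.3 ± 1.34 vs 153 ± 11.4, 4.11-fold). Antigen 43, the adhesin encoded by flu (b2000, 1260 ± 9.3 vs 29.8 ± 2.41, 41-fold), rose together with its neighbour yeeR (b2001, 65 ± 6.11 vs 5.32 ± 1.02, 10.5-fold).

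Of 23 textbook targets that Cra represses, most were higher (16 higher, 2 lower, 18 and 2 adjusted over the list alone, median log2 0.39, camera adjusted p = 9.35e-09). Besides the fructose genes these included adhE (b1241, aldehyde-alcohol dehydrogenase, 2390 ± 47.1 vs 717 ± 1.45, 3.33-fold), pfkA (b3916, phosphofructokinase, 888 ± 2.94 vs 412 ± 28.6, 2.15-fold) and epd (b2927, erythrose-4-phosphate dehydrogenase, 576 ± 0.836 vs 214 ± 4.83, 2.68-fold). The 2 members that fell were acnB (b0118, aconitase B, 1121 ± 29.3 vs 1551 ± 30.3, 1.38-fold) and mtlR (b3601, the mannitol repressor, 69.2 ± 1.75 vs 97.9 ± 6.46, 1.41-fold), the latter losing its call as deposited and with quantile scaling. Of 11 textbook targets that Cra activates, 7 fell, among them ppsA, pck (b3403, phosphoenolpyruvate carboxykinase, 77.1 ± 3.77 vs 136 ± 4.53, 1.76-fold) and icd (b1136, isocitrate dehydrogenase, 3396 ± 50.8 vs 4879 ± 109, 1.44-fold). The list passed its test (1 higher, 7 lower, 3 and 7 adjusted over the list alone, median log2 -0.78, camera adjusted p = 0.00144, adjusted p = 0.179 with an estimated correlation), and its only member past the threshold upward was cydA (b0733, a subunit of cytochrome bd oxidase, 308 ± 7.99 vs 224 ± 2.03, 1.37-fold), whose call was lost without the second Δcra glucose library. These lists come from textbook knowledge of Cra and not from these libraries.

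In central metabolism, sugar uptake and glycolysis genes rose as a list of 18 (11 higher, 1 lower, 12 and 2 adjusted over the list alone, median log2 0.38, camera adjusted p = 0.000134, adjusted p = 0.0846 with an estimated correlation). Members included fbaA (b2925, fructose-bisphosphate aldolase, 3722 ± 100.4 vs 1811 ± 83.4, 2.06-fold) and gpmM (b3612, phosphoglycerate mutase, 747 ± 19.3 vs 393 ± 19.7, 1.9-fold). Of 6 gluconeogenesis genes, ppsA, pck and fbp (b4232, fructose-1,6-bisphosphatase, 216 ± 1.36 vs 373 ± 4.64, 1.72-fold) fell (0 higher, 3 lower, median log2 -0.47, camera adjusted p = 0.00126, adjusted p = 0.0846 with an estimated correlation). The glyoxylate shunt and acetate uptake list of 8 was lower (0 higher, 6 lower, 0 and 7 adjusted over the list alone, median log2 -0.92, camera adjusted p = 0.000104, adjusted p = 0.0998 with an estimated correlation), as shown by aceA (b4015, isocitrate lyase, 1475 ± 29.5 vs 2815 ± 68.2, 1.91-fold) and acs (b4069, acetyl-CoA synthetase, 57.3 ± 1.22 vs 115 ± 3.24, 1.99-fold). TCA cycle genes were lower as well (1 higher, 12 lower of 16, median log2 -0.40, camera adjusted p = 6.37e-06, adjusted p = 0.0567 with an estimated correlation). Foremost were sdhC (b0721, a membrane subunit of succinate dehydrogenase, 301 ± 9.82 vs 1123 ± 34.7, 3.72-fold) with gltA (b0720, citrate synthase, 1200 ± 8.58 vs 2346 ± 2.35, 1.95-fold). Pyruvate dehydrogenase, acetate overflow and fermentation genes were higher (5 higher, 0 lower of 15, 3 and 0 adjusted over the list alone, median log2 0.22, camera adjusted p = 0.0227, adjusted p = 0.335 with an estimated correlation). An example was aceF (b0115, a pyruvate dehydrogenase subunit, 1271 ± 9.52 vs 728 ± 9.09, 1.75-fold) beside adhE. Pentose phosphate and Entner-Doudoroff genes were higher (5 higher, 1 lower of 12, median log2 0.23, camera adjusted p = 0.0315, adjusted p = 0.179 with an estimated correlation). Among them was pgl (b0767, 6-phosphogluconolactonase, 357 ± 11.9 vs 231 ± 4.67, 1.55-fold).

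Iron uptake genes rose (22 higher, 0 lower of 30, 24 and 1 adjusted over the list alone, median log2 0.63, camera adjusted p = 3.28e-11). Examples were fepA (b0584, the enterobactin receptor, 165 ± 17.1 vs 51 ± 6.32, 3.19-fold) and entA (b0596, an enzyme of enterobactin synthesis, 170.1 ± 5.33 vs 56 ± 1.88, 3-fold). Heat shock genes rose (13 higher, 0 lower of 15, median log2 0.82, camera adjusted p = 2.14e-08). Members included the chaperonin gene groS (b4142, 1681 ± 39.9 vs 531 ± 6.62, 3.16-fold). Curli and type 1 fimbriae genes were higher (8 higher, 0 lower of 12, 10 and 0 adjusted over the list alone, median log2 0.91, camera adjusted p = 7.33e-05). Foremost was fimA (b4314, the fimbrial major subunit, 1071 ± 36.9 vs 327 ± 4.74, 3.27-fold). Acid resistance genes were higher (6 higher, 0 lower of 10, 9 and 0 adjusted over the list alone, median log2 0.39, camera adjusted p = 0.00346, adjusted p = 0.0567 with an estimated correlation). An example was gadA (b3517, glutamate decarboxylase, 353 ± 3.93 vs 242 ± 4.92, 1.46-fold). The general stress list of RpoS held 27 genes (14 higher, 1 lower, median log2 0.25, camera adjusted p = 0.00169, adjusted p = 0.0846 with an estimated correlation). Among them was talA (b2464, transaldolase A, 369.7 ± 3.51 vs 243 ± 17.7, 1.52-fold).

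Carbon scavenging genes that depend on CRP, the cyclic AMP receptor protein, fell (1 higher, 30 lower of 58, median log2 -0.42, camera adjusted p = 1.46e-08). Members included malK (b4035, the maltose transporter ATPase, 4.92 ± 0.99 vs 33.2 ± 0.145, 5.81-fold) beside lamB and malE. Of 8 genes of fatty acid degradation, 7 fell (0 higher, 7 lower, median log2 -0.53, camera adjusted p = 0.000104). An example was fadB (b3846, 10.5 ± 0.475 vs 23.9 ± 2.53, 2.16-fold), a subunit of the beta-oxidation complex. Flagella and chemotaxis genes were lower (0 higher, 8 lower of 39, 0 and 6 adjusted over the list alone, median log2 -0.39, camera adjusted p = 0.0155, adjusted p = 0.0846 with an estimated correlation), at low levels, as in fliF (b1938, the basal body ring, 1.87 ± 0.0774 vs 4.29 ± 0.157, 1.85-fold). Amino acid synthesis genes for histidine, the branched chains, threonine, tryptophan and arginine were higher (20 higher, 4 lower of 37, 22 and 5 adjusted over the list alone, median log2 0.26, camera adjusted p = 0.000363, adjusted p = 0.22 with an estimated correlation). Among them was hisA (b2024, 256 ± 14.7 vs 123 ± 1.07, 2.07-fold). Methionine and sulphur genes were higher (14 higher, 1 lower of 20, 15 and 1 adjusted over the list alone, median log2 0.38, camera adjusted p = 6.37e-06, adjusted p = 0.0846 with an estimated correlation). Members included cysA (b2422, a sulphate transporter subunit, 496 ± 1.04 vs 278 ± 0.49, 1.78-fold).

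Nitrogen limitation genes were lower (2 higher, 6 lower of 18, median log2 -0.30, camera adjusted p = 0.0424, adjusted p = 0.22 with an estimated correlation). Examples were nac (b1988, a nitrogen regulator, 9.11 ± 0.294 vs 22.7 ± 1.8, 2.35-fold) and glnA (b3870, glutamine synthetase, 1390 ± 0.225 vs 2231 ± 98.5, 1.6-fold). Phosphate starvation genes were higher (7 higher, 0 lower of 13, 7 and 1 adjusted over the list alone, median log2 0.22, camera adjusted p = 0.0227, adjusted p = 0.0846 with an estimated correlation). Among them was pstS (b3728, the phosphate-binding protein, 156 ± 0.863 vs 122 ± 0.216, 1.27-fold). Lists not past their test were aerobic respiration (5 higher, 2 lower of 30, median 0.07, adjusted p = 0.212), ribosomal proteins (17 higher, 9 lower of 54, 17 and 10 adjusted over the list alone, median 0.04, adjusted p = 0.212) and nucleotide synthesis (4 higher, 3 lower of 23, median -0.13, adjusted p = 0.317). SOS response (4 higher, 0 lower of 18, 2 and 0 adjusted over the list alone, median 0.13, adjusted p = 0.177) and genes beside cra (3 higher, 0 lower of 6, median 0.20, adjusted p = 0.108) did not pass either. Examples were ndh (b1109, NADH dehydrogenase II, 202 ± 22.2 vs 85.2 ± 0.97, 2.35-fold), rpsI (b3230, ribosomal protein S9, 3098 ± 88.6 vs 6638 ± 637, 2.14-fold), purC (b2476, 907 ± 49.9 vs 1363 ± 5.73, 1.5-fold), dinI (b1061, 362 ± 18.1 vs 189.8 ± 11.5, 1.9-fold) and, next to the deleted gene, ilvH (b0078, 369 ± 0.549 vs 286 ± 9.19, 1.29-fold).

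The stable RNA list was not past its test either (0 higher, 1 lower of 9, median -2.51, adjusted p = 0.0888), and near-identical rRNA copies such as rrsD (b3278, 16S rRNA, 409.5 ± 559 vs 841 ± 229, adjusted p = 0.172) disagreed between the Δcra glucose libraries. Short RNAs gave the most extreme ratios, given here per library: thrV (b3273, a threonine tRNA, 0 and 0 vs 102900 and 54040), tyrU (b3977, a tyrosine tRNA, 0 and 0 vs 9802 and 5093), cyaR (b4438, a small regulatory RNA, 0 and 0 vs 1133 and 525) and omrB (b4445, a small regulatory RNA, 0 and 0 vs 416 and 955). In the same direction a gene whose identifier matched no gene name (0 and 0 vs 1067 and 845) was listed at 0 in Δcra. In the other direction stood azuC (b4663, a gene of 87 bases, 2503 and 2199 vs 0.0148 and 0.00541), which overlaps another gene while strandedness is not stated.

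In all, 1243 of 3548 genes passed an adjusted p of 0.05 on glucose, 633 higher and 610 lower in Δcra, and 182 of them changed by 2-fold or more (88 higher, 94 lower). 21 of 27 lists, not all independent, passed camera, 13 higher and 8 lower, and 7 held with an estimated correlation. The split depends on scaling: 50.9% of the called genes were higher, against 72.7% with the values as deposited, where the median of all genes shifted by 0.115, and 64.3% with quantile scaling. Calls were lost with quantile scaling for flagella, with a mean FPKM of at least 20 or without the first Δcra glucose library for pentose phosphate, and without the first WT glucose library for phosphate and fermentation. Nitrogen limitation lost its call with a pseudocount of 0.1, with at least 20 FPKM, with quantile scaling, and without the second WT glucose library or either Δcra glucose library. The count fell to 767 when only the 4 libraries compared were fitted, and to 777 or 790 without the first or second Δcra glucose library.

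The comparison of Δcra with WT on fructose asks the same with the sugar whose catabolite is known to release Cra from DNA. Iron uptake genes were among those that rose the most: fepA (1062 ± 22.1 vs 23 ± 1.98, 44.3-fold), entH (b0597, a thioesterase of enterobactin synthesis, 941 ± 34.6 vs 28.2 ± 7.39, 32.8-fold) and fiu (b0805, an iron catecholate receptor, 1149 ± 11.8 vs 37.7 ± 1.9, 29.7-fold). Succinate dehydrogenase and maltose genes were among those that fell the most, as in sdhC (86.8 ± 1.91 vs 4279 ± 406, 48.6-fold), malE (5.43 ± 0.189 vs 377 ± 7.44, 58.8-fold) and lamB (5.82 ± 1.13 vs 314 ± 24.6, 46.5-fold). The fructose operon was higher in Δcra by less than on glucose (interaction adjusted p = 4.5e-07 for fruB): fruA (2228 ± 15.1 vs 449 ± 45.8, 4.97-fold), fruB (1902 ± 70.5 vs 463 ± 14.3, 4.1-fold) and fruK (1509 ± 108 vs 404 ± 61.2, 3.74-fold). The fructose list passed with all 3 members higher (median log2 2.04, camera adjusted p = 0.00865, adjusted p = 0.154 with an estimated correlation).

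The textbook list that Cra represses was split (10 higher, 11 lower of 23, median 0.02, adjusted p = 0.917). Its members that fell included adhE (1912 ± 1.96 vs 3533 ± 14.6, 1.85-fold), glk (b2388, glucokinase, 51.9 ± 1.8 vs 148 ± 20.3, 2.81-fold) and acnB (632 ± 13.5 vs 1873 ± 200.4, 2.95-fold), and those that rose included fbaA (3261 ± 0.674 vs 2085 ± 22.2, 1.56-fold) and zwf (b1852, glucose-6-phosphate dehydrogenase, 454 ± 15.7 vs 244 ± 5.82, 1.86-fold). epd (489 ± 8.04 vs 531 ± 2.95, 1.09-fold) lost its call with the values as deposited. The list that Cra activates was lower in 10 of 11 (1 higher, 10 lower, median log2 -0.79, camera adjusted p = 0.000186, adjusted p = 0.154 with an estimated correlation). Members included pck (66.9 ± 2.26 vs 823 ± 65.2, 12.1-fold) and ppsA (73.7 ± 3.41 vs 126 ± 2.09, 1.7-fold). Its only member past the threshold upward was crp (b3357, the cyclic AMP receptor protein, 822 ± 18.5 vs 732 ± 45, 1.12-fold), whose call was lost with quantile scaling. Gluconeogenesis genes fell (0 higher, 5 lower of 6, median log2 -0.91, camera adjusted p = 0.00445, adjusted p = 0.154 with an estimated correlation). An example was maeA (b1479, NAD-malic enzyme, 189 ± 5.51 vs 395 ± 4.61, 2.08-fold) beside pck. Glyoxylate shunt and acetate uptake genes fell (0 higher, 7 lower of 8, median log2 -1.42, camera adjusted p = 0.00026, adjusted p = 0.154 with an estimated correlation). Among them were actP (b4067, the acetate permease, 6.09 ± 0.849 vs 247 ± 36.4, 34.9-fold) and acs (34.9 ± 1.92 vs 746 ± 84.6, 20.8-fold).

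TCA cycle genes fell (1 higher, 15 lower of 16, median log2 -1.94, camera adjusted p = 7e-08), and sdhA (b0723, the flavoprotein of succinate dehydrogenase, 122 ± 2.31 vs 1583 ± 118, 12.9-fold) followed sdhC. Aerobic respiration and ATP synthase genes fell (1 higher, 26 lower of 30, median log2 -0.85, camera adjusted p = 3.28e-07, adjusted p = 0.163 with an estimated correlation). Members included nuoN (b2276, a subunit of NADH dehydrogenase I, 119 ± 12.4 vs 646 ± 108, 5.35-fold). Ribosomal protein genes were higher (34 higher, 9 lower of 54, median log2 0.45, camera adjusted p = 0.0038, adjusted p = 0.154 with an estimated correlation), though rpsU (b3065, ribosomal protein S21, 10460 ± 514 vs 69700 ± 12610, 6.61-fold) and rpsI (2558 ± 25.4 vs 9924 ± 2076, 3.84-fold) were among those that fell. Carbon scavenging genes under CRP fell (3 higher, 49 lower of 58, median log2 -2.15, camera adjusted p = 1.82e-14). Examples were gatC (b2092, the galactitol permease, 221 ± 7.5 vs 7466 ± 755, 33.6-fold) and malK (0.751 ± 0.528 vs 118 ± 8.94, 69.4-fold). All 8 genes of fatty acid degradation fell (0 higher, 8 lower, median log2 -2.21, camera adjusted p = 5.25e-06). Among them was fadB (6.09 ± 0.288 vs 100.2 ± 8.85, 14.3-fold).

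Motility genes fell together (0 higher, 34 lower of 39, median log2 -2.46, camera adjusted p = 9.63e-10): fliC (b1923, flagellin, 23.6 ± 0.551 vs 354 ± 16.5, 14.4-fold), flgB (b1073, the proximal rod, 3.65 ± 0.00231 vs 137 ± 23.5, 29.5-fold) and tar (b1886, the aspartate receptor, 1.38 ± 0.247 vs 33.8 ± 2.07, 14.7-fold). All 10 acid resistance genes rose (10 higher, 0 lower, median log2 2.46, camera adjusted p = 4.12e-06). Members included hdeA (b3510, a periplasmic acid chaperone, 9539 ± 801 vs 1045 ± 16.3, 9.11-fold) and slp (b3506, 923 ± 5.45 vs 115 ± 16.2, 8-fold), a lipoprotein gene of the same island. RpoS genes rose (20 higher, 1 lower of 27, median log2 0.62, camera adjusted p = 8.09e-05). An example was gadB (b1493, glutamate decarboxylase, 1268 ± 22.2 vs 217 ± 30.9, 5.86-fold). Iron uptake genes rose (29 higher, 0 lower of 30, median log2 2.26, camera adjusted p = 3.01e-14). Curli and type 1 fimbriae genes rose (10 higher, 0 lower of 12, median log2 1.21, camera adjusted p = 0.00059). Among them was csgE (b1039, a curli assembly factor, 100 ± 2.65 vs 19.9 ± 6.74, 4.97-fold).

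Lists of central metabolism not past their test were sugar uptake and glycolysis (8 higher, 9 lower of 18, median -0.05, adjusted p = 0.917), pyruvate dehydrogenase and fermentation (6 higher, 6 lower of 15, 6 and 7 adjusted over the list alone, median -0.12, adjusted p = 0.866) and pentose phosphate (6 higher, 2 lower of 12, median 0.33, adjusted p = 0.123). Within them gpmA (b0755, phosphoglycerate mutase, 3061 ± 13.9 vs 1444 ± 7.45, 2.12-fold) and tktB (b2465, transketolase B, 459 ± 3.48 vs 169.6 ± 13, 2.7-fold) rose while frdB (b4153, fumarate reductase, 20 ± 3.07 vs 71.3 ± 11.6, 3.44-fold) and tktA (b2935, transketolase A, 562 ± 2.79 vs 1610 ± 64.3, 2.86-fold) fell. Biosynthesis and nutrient lists not past it were amino acid synthesis (16 higher, 10 lower of 37, median 0.04, adjusted p = 0.469), methionine and sulphur (6 higher, 7 lower of 20, median 0.00, adjusted p = 0.76, mean -0.09 and test down) and nucleotide synthesis (9 higher, 5 lower of 23, 11 and 5 adjusted over the list alone, median 0.17, adjusted p = 0.36). Nitrogen limitation (3 higher, 9 lower of 18, median -0.28, adjusted p = 0.197) and phosphate starvation (2 higher, 5 lower of 13, median -0.21, adjusted p = 0.197) did not pass either. Among their members ilvB (b3671, acetolactate synthase, 129 ± 2.44 vs 856 ± 44.4, 6.58-fold), metA (b4013, the first enzyme of methionine synthesis, 299 ± 17.8 vs 705 ± 24, 2.35-fold), purN (b2500, 325 ± 17.9 vs 728 ± 36.1, 2.24-fold), astA (b1747, 5.44 ± 1.12 vs 15.8 ± 0.713, 2.63-fold) and ugpA (b3452, 12.9 ± 3.1 vs 41.6 ± 0.204, 3.1-fold) fell. The rest were heat shock (5 higher, 4 lower of 15, median 0.05, adjusted p = 0.469) and SOS response (5 higher, 8 lower of 18, median -0.04, adjusted p = 0.8). Stable RNA (1 higher, 1 lower of 9, median 0.14, adjusted p = 0.982, mean 0.57 and test down) and genes beside cra (4 higher, 0 lower of 6, median 0.49, adjusted p = 0.188) did not pass either. Examples were clpB (b2592, a disaggregase, 248 ± 2.46 vs 125 ± 6.14, 1.98-fold), yebG (b1848, 174 ± 21.9 vs 499 ± 15, 2.88-fold), ffs (b0455, the RNA of the signal recognition particle, 118400 ± 17090 vs 512800 ± 489, 4.36-fold) and ilvH (375 ± 4.06 vs 174 ± 2.32, 2.15-fold).

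Per library, thrV (0 and 0 vs 21670 and 32850), tyrU (0 and 0 vs 9236 and 9115), cyaR (0 and 0 vs 5340 and 4106) and the gene with no matching name (0 and 0 vs 848 and 1492) were again listed at 0 in Δcra. ryhB (b4451, a small RNA of 95 bases that iron limitation induces, 97940 ± 14190 vs 1828 ± 107, 53.3-fold) was higher, as were flu (1278 ± 7.93 vs 36.1 ± 3.05, 34.5-fold) and yeeR (76.6 ± 1.94 vs 4.5 ± 0.16, 14.1-fold). On fructose 2229 genes passed, 1146 higher and 1083 lower in Δcra, of which 788 changed by 2-fold or more (325 higher, 463 lower). Of all calls 51.4% were higher, against 59.9% as deposited and 54.8% with quantile scaling. 14 lists passed camera, 6 higher and 8 lower, and 8 held with an estimated correlation.

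The comparison on acetate asks what Cra does in cells that must make sugars from a 2-carbon source. The fructose operon was again higher in Δcra: fruB (5599 ± 53.1 vs 6.55 ± 1.47, 749-fold), fruA (2253 ± 111 vs 20.1 ± 0.372, 107-fold) and fruK (1845 ± 64.9 vs 18.8 ± 0.241, 93.2-fold). adhE (14680 ± 499 vs 666 ± 16.8, 22-fold) and the aromatic synthesis gene tyrA (b2600, 3621 ± 144 vs 200.3 ± 8.96, 18-fold) also rose. ppsA (59.1 ± 0.565 vs 1290 ± 66.7, 21.5-fold) and fbp (112 ± 1.04 vs 909.8 ± 52, 8.03-fold), both enzymes of gluconeogenesis, fell. The fructose list passed with all 3 members higher (median log2 6.74, camera adjusted p = 0.000384, adjusted p = 0.0956 with an estimated correlation).

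The textbook list that Cra represses rose (19 higher, 2 lower of 23, median log2 1.24, camera adjusted p = 4.74e-08). Members included epd (1685 ± 18.4 vs 127 ± 0.213, 13.2-fold), fbaA (7050 ± 74.9 vs 893 ± 43.6, 7.9-fold) and pgk (b2926, phosphoglycerate kinase, 4896 ± 112 vs 1353 ± 19, 3.62-fold). Its members that fell were acnB (863 ± 7.9 vs 3611 ± 188, 4.18-fold) and eda (b1850, the Entner-Doudoroff aldolase, 243 ± 0.308 vs 356 ± 6.5, 1.46-fold). The list that Cra activates fell (0 higher, 10 lower of 11, median log2 -0.54, camera adjusted p = 0.000246, adjusted p = 0.165 with an estimated correlation), while aceA (17190 ± 193 vs 18130 ± 1144, adjusted p = 0.382) did not pass. Sugar uptake and glycolysis genes rose (14 higher, 3 lower of 18, median log2 1.06, camera adjusted p = 0.000152, adjusted p = 0.14 with an estimated correlation). An example was gpmM (566 ± 15.8 vs 58.7 ± 3, 9.5-fold). Gluconeogenesis genes fell (1 higher, 4 lower of 6, median log2 -0.70, camera adjusted p = 0.027, adjusted p = 0.215 with an estimated correlation). Among them was pck (1247 ± 5.2 vs 1905 ± 17.8, 1.53-fold), while maeB (b2463, NADP-malic enzyme, 313 ± 9.85 vs 255 ± 4.85, 1.22-fold) rose. Glyoxylate shunt and acetate uptake genes fell (0 higher, 7 lower of 8, median log2 -0.57, camera adjusted p = 0.00802, adjusted p = 0.268 with an estimated correlation). Members included actP (466 ± 2.2 vs 1095 ± 10.7, 2.35-fold) and acs (1627 ± 4.57 vs 2529 ± 241, 1.55-fold).

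TCA cycle genes fell (2 higher, 11 lower of 16, 2 and 12 adjusted over the list alone, median log2 -0.60, camera adjusted p = 0.000759, adjusted p = 0.147 with an estimated correlation). Foremost was sdhC (764 ± 52.7 vs 6847 ± 735, 8.94-fold). Aerobic respiration genes fell (4 higher, 21 lower of 30, 7 and 21 adjusted over the list alone, median log2 -0.89, camera adjusted p = 0.00107, adjusted p = 0.322 with an estimated correlation). An example was nuoN (112 ± 4.89 vs 574 ± 33, 5.08-fold). Carbon scavenging genes under CRP fell (5 higher, 38 lower of 58, 6 and 38 adjusted over the list alone, median log2 -0.60, camera adjusted p = 0.000152). Among them were malK (23.2 ± 2.93 vs 175 ± 1.54, 7.3-fold) and tnaB (b3709, a tryptophan transporter, 17.7 ± 3 vs 115 ± 0.586, 6.26-fold). All 8 genes of fatty acid degradation fell (0 higher, 8 lower, median log2 -0.94, camera adjusted p = 0.000705). Members included fadB (168 ± 3.68 vs 386 ± 41, 2.29-fold). Motility genes fell (2 higher, 26 lower of 39, median log2 -1.31, camera adjusted p = 0.000705, adjusted p = 0.0514 with an estimated correlation). An example was flgB (9.21 ± 5.27 vs 70.9 ± 5.31, 7.56-fold), and the chemotaxis genes cheY and trg rose.

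All 10 acid resistance genes fell (0 higher, 10 lower, median log2 -1.72, camera adjusted p = 5.52e-05), opposite to their direction on fructose: hdeD (b3511, 94.7 ± 7.43 vs 528 ± 42.1, 5.52-fold), gadC (b1492, the glutamate antiporter, 138 ± 8.16 vs 743 ± 14.6, 5.34-fold) and hdeA (2191 ± 75.2 vs 4390 ± 34.9, 2-fold). Amino acid synthesis genes fell (9 higher, 27 lower of 37, median log2 -0.93, camera adjusted p = 0.000705, adjusted p = 0.283 with an estimated correlation). Among them were ilvB (78.5 ± 1.11 vs 664 ± 44.4, 8.36-fold) and argC (b3958, 64.6 ± 1.78 vs 326 ± 28.2, 4.98-fold), against trpC (b1262, 408 ± 1.66 vs 107 ± 1.28, 3.8-fold). Methionine and sulphur genes fell (0 higher, 11 lower of 20, median log2 -0.31, camera adjusted p = 0.00188, adjusted p = 0.254 with an estimated correlation). Members included metA (94.7 ± 2.02 vs 479.9 ± 3.96, 5.03-fold). Iron uptake genes rose (23 higher, 1 lower of 30, median log2 1.36, camera adjusted p = 4.74e-08). An example was fepA (1001 ± 12.4 vs 119 ± 3.91, 8.37-fold). Curli and type 1 fimbriae genes split within their list (7 higher, 4 lower, median log2 2.22, camera adjusted p = 0.0402, adjusted p = 0.147 with an estimated correlation): the 7 fim genes rose, for example fimA (4609 ± 154 vs 374 ± 15.9, 12.3-fold), and csgD, csgF, csgG and csgE (12.7 ± 4.08 vs 20.3 ± 1.24, 1.58-fold) fell. That list lost its call with quantile scaling, with no filter, with a mean FPKM of at least 20 and without any one of the 4 WT glucose and WT fructose libraries.

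Lists not past their test were pyruvate dehydrogenase and fermentation (4 higher, 8 lower of 15, median -0.23, adjusted p = 0.511), pentose phosphate (6 higher, 4 lower of 12, median 0.27, adjusted p = 0.262) and ribosomal proteins (11 higher, 26 lower of 54, median -0.20, adjusted p = 0.122). RpoS (5 higher, 12 lower of 27, median -0.13, adjusted p = 0.492) and nucleotide synthesis (8 higher, 11 lower of 23, 9 and 11 adjusted over the list alone, median -0.11, adjusted p = 0.49) did not pass either. Among their members frdB (24.8 ± 4.66 vs 125 ± 5.01, 4.92-fold), tktA (743 ± 8.92 vs 1305 ± 30.9, 1.76-fold), rpsI (1199 ± 67.3 vs 8188 ± 241, 6.83-fold), gadB (228 ± 7.86 vs 976 ± 86.1, 4.27-fold) and carA (b0032, 167 ± 7.55 vs 517 ± 1.22, 3.08-fold) fell. The others were nitrogen limitation (2 higher, 9 lower of 18, 2 and 11 adjusted over the list alone, median -0.36, adjusted p = 0.0519), phosphate starvation (1 higher, 7 lower of 13, median -0.25, adjusted p = 0.0608), heat shock (6 higher, 2 lower of 15, median 0.07, adjusted p = 0.25) and SOS response (7 higher, 1 lower of 18, median 0.18, adjusted p = 0.172). Stable RNA (1 higher, 1 lower of 9, median 1.00, adjusted p = 0.734, mean -0.35 and test up) and genes beside cra (3 higher, 1 lower of 6, median 0.31, adjusted p = 0.262) did not pass either. Of these, glnA (439.7 ± 10.4 vs 1051 ± 61.9, 2.39-fold) and ugpA (12.8 ± 0.306 vs 59.4 ± 5.66, 4.38-fold) fell while clpB (167 ± 1.06 vs 89.5 ± 4.9, 1.86-fold), ruvB (b1860, a Holliday junction helicase, 89.7 ± 0.172 vs 44.9 ± 1.77, 1.98-fold) and ilvH (232 ± 14 vs 104 ± 5.35, 2.22-fold) rose.

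Short genes listed at 0 in Δcra on acetate included thrV (0 and 0 vs 23670 and 14800) and cyaR (0 and 0 vs 1543 and 3596), per library, while ryhB (218700 ± 18750 vs 8724 ± 1023, 25.1-fold) was higher. Antigen 43 was again higher, flu (1759 ± 14.9 vs 46.3 ± 1.29, 37.2-fold). On acetate 2175 genes passed, 1044 higher and 1131 lower in Δcra, of which 714 changed by 2-fold or more (322 higher, 392 lower). Of all calls 48% were higher, against 46% as deposited and 51.2% with quantile scaling. 16 lists passed camera, 5 higher and 11 lower, and 5 held with an estimated correlation.

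**Figure D2:**
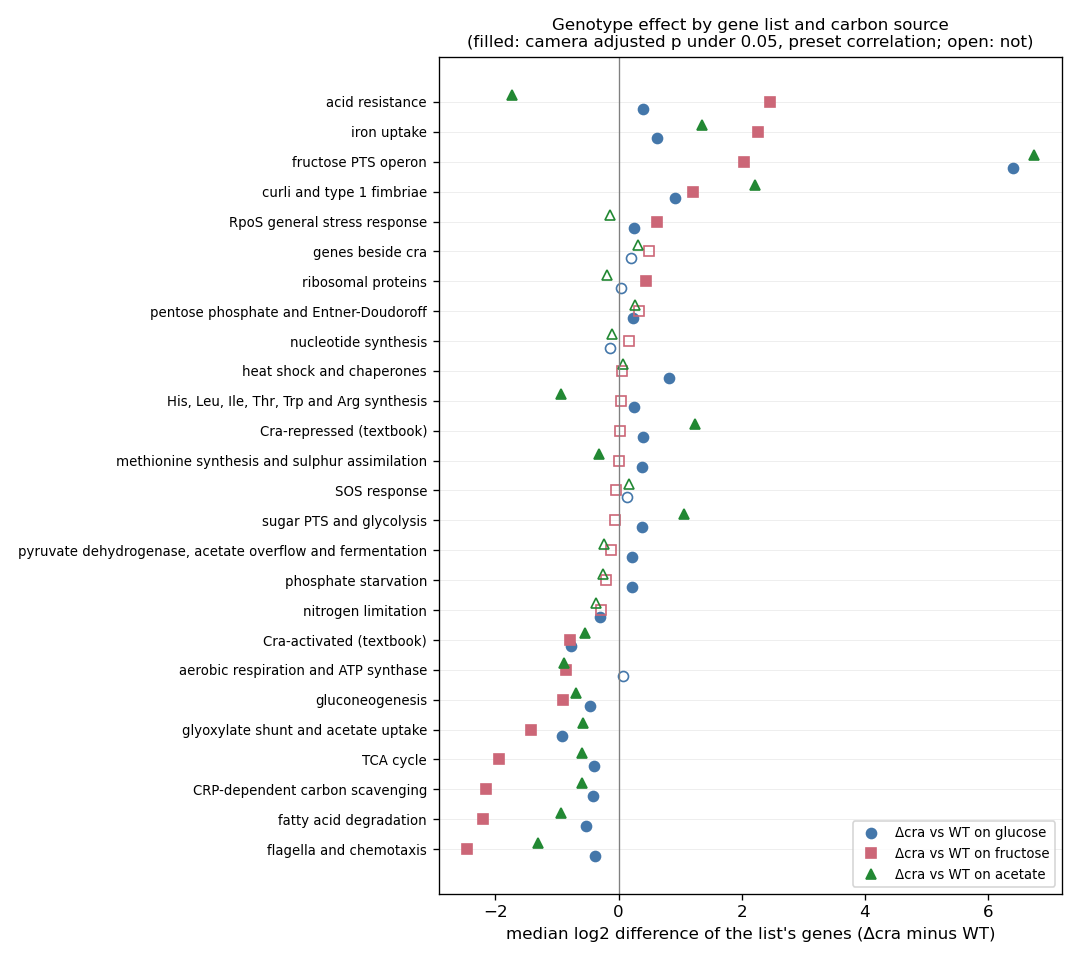
Median log2 difference of Δcra minus WT for 26 gene lists on glucose (blue circles), fructose (red squares) and acetate (green triangles), filled where the camera adjusted p was under 0.05. Acid resistance lies at 2.46 on fructose and -1.72 on acetate, and iron uptake is above 0 on all 3 sources.

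WT fructose against WT glucose asks how cells with Cra differ between the sugars. The fructose operon rose: fruB (463 ± 14.3 vs 17.4 ± 1.25, 25.2-fold), fruK (404 ± 61.2 vs 22.8 ± 0.0537, 16.9-fold) and fruA (449 ± 45.8 vs 30.4 ± 3.15, 14.3-fold), given as fructose against glucose (median log2 4.08, camera adjusted p = 0.000795, adjusted p = 0.104 with an estimated correlation, all 3 higher). Motility genes rose with it (31 higher, 0 lower of 39, 32 and 0 adjusted over the list alone, median log2 1.57, camera adjusted p = 4.14e-09). Among them were cheW (b1887, a chemotaxis coupling protein, 159 ± 3.47 vs 11.1 ± 0.898, 13.2-fold) and fliC (354 ± 16.5 vs 36.6 ± 1.3, 9.44-fold). ptsG (b1101, the glucose permease, 400 ± 40.4 vs 1501 ± 12.8, 3.75-fold) and ppsA (126 ± 2.09 vs 346 ± 7.19, 2.74-fold) fell. Carbon scavenging genes under CRP rose (47 higher, 5 lower of 58, median log2 1.3, camera adjusted p = 6.06e-11). Members included glpF (b3927, the glycerol channel, 70.4 ± 6.61 vs 3.98 ± 2.05, 14.9-fold) and cstA (b0598, a carbon starvation transporter, 783 ± 118 vs 85.9 ± 6.7, 8.99-fold). All 8 genes of fatty acid degradation rose (8 higher, 0 lower, median log2 1.23, camera adjusted p = 5.6e-05). An example was fadB (100.2 ± 8.85 vs 23.9 ± 2.53, 4.06-fold).

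The list that Cra represses was higher in 17 of 23 (17 higher, 5 lower, median log2 0.58, camera adjusted p = 0.000243, adjusted p = 0.102 with an estimated correlation). Among them was adhE (3533 ± 14.6 vs 717 ± 1.45, 4.92-fold). Glycolysis genes were higher (12 higher, 5 lower of 18, median log2 0.36, camera adjusted p = 0.0232, adjusted p = 0.365 with an estimated correlation). Members included pykA (b1854, pyruvate kinase II, 538 ± 12.6 vs 233 ± 8.03, 2.3-fold). Glyoxylate shunt and acetate uptake genes were higher (6 higher, 1 lower of 8, median log2 0.32, camera adjusted p = 0.0234, adjusted p = 0.393 with an estimated correlation). Examples were actP (247 ± 36.4 vs 19.7 ± 0.89, 11.9-fold) and acs (746 ± 84.6 vs 115 ± 3.24, 6.43-fold). TCA cycle genes were higher (10 higher, 3 lower of 16, median log2 0.31, camera adjusted p = 0.0232, adjusted p = 0.365 with an estimated correlation). Among them was sdhC (4279 ± 406 vs 1123 ± 34.7, 3.8-fold). Pyruvate dehydrogenase and fermentation genes were higher (10 higher, 1 lower of 15, median log2 0.33, camera adjusted p = 0.0168, adjusted p = 0.393 with an estimated correlation). Members included frdB (71.3 ± 11.6 vs 25.9 ± 0.987, 2.67-fold). Aerobic respiration genes were higher (19 higher, 2 lower of 30, 21 and 3 adjusted over the list alone, median log2 0.53, camera adjusted p = 0.000154, adjusted p = 0.365 with an estimated correlation). An example was nuoM (b2277, 521 ± 69.6 vs 207 ± 5.49, 2.5-fold). Phosphate starvation genes were higher (7 higher, 1 lower of 13, 8 and 1 adjusted over the list alone, median log2 0.39, camera adjusted p = 0.015, adjusted p = 0.102 with an estimated correlation). Among them was pstS (290.3 ± 4.49 vs 122 ± 0.216, 2.37-fold).

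Ribosomal protein genes were lower (8 higher, 36 lower of 54, 8 and 37 adjusted over the list alone, median log2 -0.66, camera adjusted p = 1.9e-05, adjusted p = 0.0824 with an estimated correlation). Members included rplL (b3986, ribosomal protein L7/L12, 2578 ± 321 vs 10560 ± 1101, 4.1-fold), while rpsU (69700 ± 12610 vs 10740 ± 6280, 7.07-fold) rose. Nucleotide synthesis genes were lower (4 higher, 15 lower of 23, 5 and 15 adjusted over the list alone, median log2 -0.28, camera adjusted p = 0.03, adjusted p = 0.419 with an estimated correlation). Examples were purC (616 ± 27.4 vs 1363 ± 5.73, 2.21-fold) and carA (518 ± 5.23 vs 1124 ± 22.1, 2.17-fold), and the list lost its call with quantile scaling, with at least 20 FPKM and without the second WT fructose library. Iron uptake genes were lower (2 higher, 20 lower of 30, 2 and 21 adjusted over the list alone, median log2 -0.47, camera adjusted p = 0.000302, adjusted p = 0.101 with an estimated correlation). Among them was fiu (37.7 ± 1.9 vs 84.2 ± 2.01, 2.21-fold). Lists not past their test were the one Cra activates (5 higher, 2 lower of 11, median 0.12, adjusted p = 0.314), gluconeogenesis (3 higher, 2 lower of 6, median 0.27, adjusted p = 0.399) and pentose phosphate (3 higher, 4 lower of 12, median -0.18, adjusted p = 0.704, mean 0.02 and test down). RpoS (7 higher, 11 lower of 27, median -0.05, adjusted p = 0.399) and acid resistance (1 higher, 6 lower of 10, 1 and 7 adjusted over the list alone, median -0.41, adjusted p = 0.1) did not pass either. Of their members pck (823 ± 65.2 vs 136 ± 4.53, 6.01-fold) and tktA (1610 ± 64.3 vs 696 ± 16, 2.31-fold) rose, and osmC (b1482, 303 ± 44 vs 719 ± 12, 2.38-fold) and hdeA (1045 ± 16.3 vs 2538 ± 178, 2.43-fold) fell.

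Also not past it were amino acid synthesis (12 higher, 18 lower of 37, median -0.16, adjusted p = 0.214), methionine and sulphur (8 higher, 7 lower of 20, median 0.07, adjusted p = 0.636) and nitrogen limitation (4 higher, 6 lower of 18, median -0.04, adjusted p = 0.62). Heat shock (8 higher, 4 lower of 15, 8 and 5 adjusted over the list alone, median 0.22, adjusted p = 0.18) and SOS response (8 higher, 3 lower of 18, median 0.25, adjusted p = 0.294) did not pass either. Of these, argG (b3172, 411 ± 9.08 vs 979.6 ± 8.02, 2.38-fold) and glnL (b3869, 52.9 ± 3.96 vs 128 ± 3.71, 2.39-fold) fell, and metA (705 ± 24 vs 406 ± 0.825, 1.74-fold), groS (1260 ± 83.3 vs 531 ± 6.62, 2.37-fold) and yebG (499 ± 15 vs 173 ± 3.35, 2.88-fold) rose. The last were curli and type 1 fimbriae (5 higher, 2 lower of 12, median 0.19, adjusted p = 0.399), stable RNA (0 higher, 5 lower of 9, median -6.39, adjusted p = 0.0736) and genes beside cra (0 higher, 4 lower of 6, median -0.33, adjusted p = 0.214). In them csgG (b1037, 19.8 ± 1.07 vs 40.9 ± 4.79, 2.01-fold) and ilvH (174 ± 2.32 vs 286 ± 9.19, 1.64-fold) fell. The rRNA copy rrsD (6.38 ± 1.03 vs 841 ± 229) was lower, in a list that only checks library composition. Listed at 0 on fructose were pheU (b4134, a phenylalanine tRNA, 0 and 0 vs 16520 and 12280), omrB (0 and 0 vs 416 and 955) and micF (b4439, a small regulatory RNA, 0 and 0 vs 593 and 423), per library. In all 2139 genes passed, 1017 higher and 1122 lower on fructose, of which 613 changed by 2-fold or more (353 higher, 260 lower). Of all calls 47.5% were higher, against 54.1% as deposited and 52.5% with quantile scaling. 14 lists passed camera, 11 higher and 3 lower, and 3 held with an estimated correlation.

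WT acetate against WT glucose asks how cells with Cra differ between a gluconeogenic source and glucose. Genes of acetate use rose, actP (1095 ± 10.7 vs 19.7 ± 0.89, 53-fold), acs (2529 ± 241 vs 115 ± 3.24, 21.8-fold) and aceA (18130 ± 1144 vs 2815 ± 68.2, 6.43-fold), here as acetate against glucose, and with them glcD (b2979, glycolate oxidase, 429 ± 14.8 vs 8.65 ± 0.558, 44.6-fold). The glyoxylate shunt and acetate uptake list rose (7 higher, 1 lower of 8, median log2 2.82, camera adjusted p = 5.13e-05, adjusted p = 0.135 with an estimated correlation). Tryptophanase, tnaA (b3708, 456 ± 16.1 vs 7.51 ± 1.03, 53.8-fold), and lsrA (b1513, an autoinducer-2 transporter subunit, 163 ± 12.2 vs 2.5 ± 1.38, 48.7-fold) rose within the carbon scavenging list under CRP, which rose (47 higher, 5 lower of 58, median log2 2.37, camera adjusted p = 8.39e-13). gpmM (58.7 ± 3 vs 393 ± 19.7, 6.6-fold) and ptsG (271 ± 5.06 vs 1501 ± 12.8, 5.52-fold) fell the furthest among long protein genes of glycolysis.

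The list that Cra represses fell (5 higher, 16 lower of 23, 5 and 17 adjusted over the list alone, median log2 -0.59, camera adjusted p = 0.00437, adjusted p = 0.166 with an estimated correlation). Members included tpiA (b3919, triosephosphate isomerase, 543 ± 16.1 vs 1434 ± 54.4, 2.64-fold). The list that Cra activates rose (10 higher, 0 lower of 11, median log2 1.28, camera adjusted p = 1.08e-05, adjusted p = 0.133 with an estimated correlation). Examples were pck (1905 ± 17.8 vs 136 ± 4.53, 13.9-fold) and ppsA (1290 ± 66.7 vs 346 ± 7.19, 3.71-fold). Gluconeogenesis genes rose (5 higher, 1 lower of 6, median log2 1.44, camera adjusted p = 0.00295, adjusted p = 0.133 with an estimated correlation). Among them was fbp (909.8 ± 52 vs 373 ± 4.64, 2.43-fold). Glycolysis genes fell (3 higher, 12 lower of 18, 4 and 12 adjusted over the list alone, median log2 -0.87, camera adjusted p = 0.0136, adjusted p = 0.253 with an estimated correlation), and the list lost its call with quantile scaling. TCA cycle genes rose (14 higher, 0 lower of 16, 15 and 0 adjusted over the list alone, median log2 1.22, camera adjusted p = 5.75e-07). Members included sdhC (6847 ± 735 vs 1123 ± 34.7, 6.08-fold). Aerobic respiration genes rose (18 higher, 6 lower of 30, median log2 0.49, camera adjusted p = 0.0125, adjusted p = 0.484 with an estimated correlation). An example was nuoM (466 ± 67.8 vs 207 ± 5.49, 2.23-fold). All 8 genes of fatty acid degradation rose (8 higher, 0 lower, median log2 2.56, camera adjusted p = 2.13e-06). Among them was fadB (386 ± 41 vs 23.9 ± 2.53, 15.5-fold).

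Motility genes rose (23 higher, 1 lower of 39, median log2 0.83, camera adjusted p = 0.000522). Members included cheW (40.7 ± 3.88 vs 11.1 ± 0.898, 3.44-fold). Acid resistance genes rose (9 higher, 0 lower of 10, 10 and 0 adjusted over the list alone, median log2 1.28, camera adjusted p = 6.12e-05). An example was gadC (743 ± 14.6 vs 178 ± 2.23, 4.15-fold). Iron uptake genes rose (21 higher, 3 lower of 30, median log2 0.96, camera adjusted p = 6.73e-06). Among them was entE (b0594, 359 ± 20.3 vs 75.4 ± 5.13, 4.71-fold). Ribosomal protein genes fell (6 higher, 40 lower of 54, median log2 -0.83, camera adjusted p = 1.12e-06). Members included rplL (1884 ± 124 vs 10560 ± 1101, 5.59-fold), while rpsU (54510 ± 3581 vs 10740 ± 6280, 5.57-fold) rose. Amino acid synthesis genes fell (4 higher, 25 lower of 37, median log2 -0.69, camera adjusted p = 6.12e-05, adjusted p = 0.241 with an estimated correlation). An example was thrC (b0004, 293 ± 14.2 vs 1068 ± 19.8, 3.63-fold). Nucleotide synthesis genes fell (1 higher, 19 lower of 23, median log2 -0.62, camera adjusted p = 0.000109, adjusted p = 0.195 with an estimated correlation). Among them was purC (495 ± 4.68 vs 1363 ± 5.73, 2.75-fold). Heat shock genes fell (2 higher, 10 lower of 15, median log2 -0.52, camera adjusted p = 0.0173, adjusted p = 0.195 with an estimated correlation). Members included dnaK (b0014, 404 ± 6.33 vs 793 ± 14.4, 1.96-fold).

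Lists not past their test were the fructose operon (0 higher, 3 lower of 3, median -0.57, adjusted p = 0.117), pyruvate dehydrogenase and fermentation (8 higher, 5 lower of 15, 8 and 6 adjusted over the list alone, median 0.33, adjusted p = 0.366), pentose phosphate (3 higher, 6 lower of 12, median -0.45, adjusted p = 0.27) and RpoS (14 higher, 7 lower of 27, 15 and 7 adjusted over the list alone, median 0.25, adjusted p = 0.175). Methionine and sulphur (4 higher, 12 lower of 20, 5 and 12 adjusted over the list alone, median -0.29, adjusted p = 0.114) did not pass either. Of their members fruB (6.55 ± 1.47 vs 17.4 ± 1.25, 2.46-fold) and zwf (149 ± 0.372 vs 337 ± 10.9, 2.25-fold) fell, and frdB (125 ± 5.01 vs 25.9 ± 0.987, 4.69-fold) and treA (b1197, periplasmic trehalase, 79.4 ± 4.2 vs 33 ± 6.27, 2.38-fold) rose. Also not past it were nitrogen limitation (10 higher, 6 lower of 18, median 0.52, adjusted p = 0.265, mean -0.01 and test up), phosphate starvation (5 higher, 5 lower of 13, median -0.08, adjusted p = 0.53, mean 0.29 and test up), SOS response (6 higher, 4 lower of 18, median 0.21, adjusted p = 0.556) and curli and type 1 fimbriae (3 higher, 3 lower of 12, median 0.18, adjusted p = 0.667, mean -0.09 and test up). Stable RNA (0 higher, 4 lower of 9, median -6.37, adjusted p = 0.258) and genes beside cra (0 higher, 4 lower of 6, median -0.53, adjusted p = 0.0929) did not pass either. In these ugpA (59.4 ± 5.66 vs 13 ± 0.549, 4.31-fold) rose and ilvH (104 ± 5.35 vs 286 ± 9.19, 2.74-fold) fell, and in the composition check rrsD (7.1 ± 3.12 vs 841 ± 229) was lower. In all 2259 genes passed, 1042 higher and 1217 lower on acetate, of which 842 changed by 2-fold or more (490 higher, 352 lower). 16 lists passed camera, 10 higher and 6 lower, and 7 held with an estimated correlation.

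Between Δcra fructose and Δcra glucose 787 genes passed, 306 higher and 481 lower on fructose, 177 by 2-fold or more. Without the first Δcra glucose library or the first Δcra fructose library the count was 524 each time. The fructose operon did not pass in this comparison, as in fruB (1902 ± 70.5 vs 2340 ± 158, adjusted p = 0.124), while ptsG (246 ± 2.9 vs 920.1 ± 1.3, 3.73-fold) fell and fepA (1062 ± 22.1 vs 165 ± 17.1, 6.42-fold) and hdeA (9539 ± 801 vs 3598 ± 421, 2.66-fold) rose. The share of calls that were higher moved from 38.9% to 50.3% with the values as deposited. Between Δcra acetate and Δcra glucose 2048 genes passed, 932 higher and 1116 lower, 711 by 2-fold or more, with acs (1627 ± 4.57 vs 57.3 ± 1.22, 28-fold) and pck (1247 ± 5.2 vs 77.1 ± 3.77, 16-fold) higher and ptsG (119 ± 6.84 vs 920.1 ± 1.3, 7.7-fold) lower. Here ppsA (59.1 ± 0.565 vs 54.1 ± 1.24, adjusted p = 0.0751) did not pass, and the share higher moved from 45.5% to 30.8% as deposited.

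WT acetate and WT fructose differed in 1160 genes, 535 higher and 625 lower on acetate, 259 by 2-fold or more, and in 596 when only those 4 libraries were fitted. fruB (6.55 ± 1.47 vs 463 ± 14.3, 62.1-fold) and fliC (75.6 ± 5.01 vs 354 ± 16.5, 4.64-fold) were lower on acetate and ppsA (1290 ± 66.7 vs 126 ± 2.09, 10.2-fold) and aceA (18130 ± 1144 vs 3242 ± 261, 5.6-fold) higher. The share higher moved from 46.1% to 30.8% as deposited. The genes named for these 3 comparisons were picked from those already named above, after their values were seen.

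A difference between the effects of Cra on 2 sources needs a test of the interaction itself, which was made for each pair of sources. The largest F values, which a small spread raises, were for adhE (log2 Δcra over WT 1.74, -0.89 and 4.46 on glucose, fructose and acetate), epd (1.42, -0.12 and 3.72) and aroF (b2601, aromatic synthesis, -0.26, 0.64 and 3.93). ppsA was lower on every source by different amounts (-2.66, -0.76 and -4.42), the porin gene nmpC (b0553) fell mainly on fructose (-1.24, -4.18 and 0.24), and entA rose most there (1.58, 4.61 and 2.48). The effect differed between fructose and glucose for 1720 genes (858 higher and 862 lower on fructose), of which 726 by 2-fold or more. Between acetate and glucose it differed for 1690 genes (813 and 877), of which 639 by 2-fold or more, and between acetate and fructose for 1210 (567 and 643), of which 472. The F test over the 2 interaction contrasts passed for 2129 of 3548 genes.

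Over all sources, with carbon source as a covariate, the clearest changes with genotype besides cra, thrV, cyaR and the gene with no matching name were flu (antigen 43, log2 5.23, adjusted p = 9.81e-12) and yeeR (its neighbour, log2 3.33, adjusted p = 1.23e-06). They were followed by clpB (the disaggregase, log2 0.93, adjusted p = 2.63e-06), orn (b4162, oligoribonuclease, log2 1.18, adjusted p = 6.65e-06) and metJ (b3938, the methionine repressor, log2 1.39, adjusted p = 8.03e-06). 1753 genes passed, 849 higher and 904 lower in Δcra, of which 408 changed by 2-fold or more (148 higher, 260 lower).

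The effects of the genotype on 2 sources share no library, but their calls share the estimate of each gene's spread, which came from all 12 libraries. They correlated at r = 0.316 (rho 0.366) for glucose and fructose, 0.338 (0.288) for glucose and acetate and 0.561 (0.641) for fructose and acetate, over 3547 genes without cra. On glucose and fructose, 387 genes were higher in both, where independence gives 204.5, 347 were lower in both against 185.8, and 197 moved in opposite directions. On glucose and acetate 330 were higher in both against 186.3, 317 lower against 194, and 241 opposite. On fructose and acetate 760 were higher in both against 337.3, 759 lower against 344.7, and 184 opposite. On all 3 sources 278 genes were higher in Δcra, where independence gives 60.2, among them fruB, fruA and fepA, and 262 were lower, against 59.4, among them ppsA, sdhC and malE. Genes with a small spread pass more easily on every source, so the counts under independence are not a chance level. Genes are not independent replicates either, so no p is given for these overlaps.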

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

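The tests of exchanged WT fructose and WT acetate labels and of flu and yeeR, the spread criterion for fragment length and the splits of whole groups were chosen only after the results were seen. What marked each value of the next 2 paragraphs was a tested difference between groups, the interaction of genotype and carbon source.

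The genotype effect differed between fructose and glucose for 1720 genes, between acetate and glucose for 1690 and between acetate and fructose for 1210, and the F test passed for 2129. The largest F values were those of adhE (3566), epd (2853), aroF (2568), nmpC (1463), tyrA (1353), ppsA (1182), entA (1162), gatC (1079), entF (1073) and pheA (1048), at adjusted p of 1.09e-08 to 1.25e-07. Effects on glucose, fructose and acetate, not given above, were -0.41, 1.02 and 4.17 for tyrA, -0.54, -5.07 and -1.63 for gatC, 1.34, 4.42 and 2.35 for entF, and -0.14, -0.14 and 2.50 for pheA.

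Lists whose median genotype effect was higher or lower on fructose than on glucose, held with an estimated correlation, were flagella (log2 -2.10), acid resistance (1.98), CRP (-1.71), fatty acid degradation (-1.57) and iron uptake (1.85). The other lists that passed, with the p reached with an estimated correlation, were the fructose operon (-4.28, adjusted p = 0.094), Cra-repressed (-0.64, adjusted p = 0.0506), glycolysis (-0.48, adjusted p = 0.287), glyoxylate (-0.49, adjusted p = 0.311), TCA (-1.32, adjusted p = 0.0506), aerobic respiration (-1.11, adjusted p = 0.131), RpoS (0.30, adjusted p = 0.131), methionine (-0.42, adjusted p = 0.255), phosphate (-0.39, adjusted p = 0.104) and heat shock (-0.44, adjusted p = 0.207). Between acetate and glucose acid resistance held (-2.01), and others were Cra-repressed (0.71, adjusted p = 0.108), glycolysis (0.73, adjusted p = 0.218), aerobic respiration (-1, adjusted p = 0.247), ribosomal (-0.32, adjusted p = 0.246), flagella (-0.92, adjusted p = 0.146), RpoS (-0.37, adjusted p = 0.247), amino acids (-0.96, adjusted p = 0.218), methionine (-0.78, adjusted p = 0.108), phosphate (-0.73, adjusted p = 0.108), iron (0.70, adjusted p = 0.108) and heat shock (-0.63, adjusted p = 0.208). Between acetate and fructose the fructose operon (4.64), Cra-repressed (1.37), ribosomal (-0.53), flagella (1.21), RpoS (-0.60), acid resistance (-4.21), CRP (1.65), fatty acids (1.25) and iron (-1.12) held, and others were glycolysis (1.08, adjusted p = 0.0502), glyoxylate (1.15, adjusted p = 0.212), TCA (1.58, adjusted p = 0.0617), aerobic respiration (0.45, adjusted p = 0.505), amino acids (-0.82, adjusted p = 0.184), methionine (-0.39, adjusted p = 0.178) and SOS (0.41, adjusted p = 0.0894).

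Over all carbon sources 1753 genes passed for genotype. Of 100 splits of the 12 libraries drawn from 462, only the real one called as many, and the highest other called 907. That other split keeps groups whole and parts only fructose libraries by genotype, so 907 is no chance level. Most splits part replicates not shown to be separate cultures, so the bound set beforehand (under 5 of 100) was too loose. Only 10 keep groups whole (highest other 907), too few for a share under 0.05.

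Genes under 200 bases gave the most extreme ratios between the genotypes, and held less of the FPKM in Δcra on each source. As a set, they also differed between the libraries of one group: the median replicate difference was 0.326 in log2 against 0.103 for genes of 300 bases or longer, a ratio of 3.16, and a 0 in 1 of 2 libraries occurred 187 times in 101 of 193 short genes against 19 times in 15 of 3066 long ones. That is consistent with estimates that fail for genes shorter than the sequenced fragments, but does not describe thrV and cyaR, which had values in all 6 WT libraries and were at 0 in all 6 Δcra libraries. A different fragment length between the genotypes cannot be told apart: the medians of 79 short genes never at 0 were -0.468 ± 0.24 (SE), 0.329 ± 0.186 and 0.227 ± 0.116 on glucose, fructose and acetate, which met the bound set beforehand against it (a change of sign, or within 0.25 of 0), but each lay within 2 SE of 0, so the bound was wrong to ignore their spread. The length that FPKM subtracts from genes, read from the steps of low values, was 225 to 270 bases in WT and 235 to 250 in Δcra, which shows no such difference but varied within a group (235 and 270 in WT glucose), and an effect of the genotype on short RNAs stays open, untested.

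WT fructose lay nearer WT acetate (r = 0.957) than WT glucose (0.933), while Δcra fructose lay nearer Δcra glucose (0.973) than Δcra acetate (0.906). An exchange of the WT fructose and WT acetate labels is argued against by fruB, fruK and fruA, each higher in WT fructose by a log2 of at least 4.35, and one of Δcra fructose and Δcra glucose by ptsG, lower on fructose in Δcra (log2 -1.90) and in WT (-1.91). Nor does the lower depth of WT glucose account for it, since with each library thinned to 2.02 M fragments over 2796 genes the difference in r was at least 0.017 in 20 draws, against 0.02 without thinning. A response to fructose that depends on Cra may underlie the pattern, a hypothesis found on these data and not tested further.

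flu was higher in Δcra by 5.36, 5.11 and 5.22 in log2 on glucose, fructose and acetate, and its neighbour yeeR by 3.39, 3.82 and 2.78. The ranges of these effects were 0.25 for flu (F test adjusted p = 0.132) and 1.04 for yeeR (0.00889), in tests made first for both genes and then apart. They do not decide for a state of the strain that the carbon source does not set, nor against it: both genes were picked from a ranking over all sources, which favours equal effects, and yeeR lay near the floor in WT (4.39 to 6.42). Such a state, known for flu from textbooks, and an effect of Cra itself cannot be told apart here, and both stay open.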

How the results depend on the processing

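The alternatives chosen only after the data were seen were the limit to genes of 300 bases or longer never listed at 0 and voom on recovered fragments. Of 662 named gene results, 548 kept their side of the threshold under every setting run for them, and 91 changed side with at least 1 library left out. A lone library left in a group is assumed to vary like those of the other groups. Depth limits genes with few fragments most in WT glucose.

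With an absolute log2 change of at least 1 the counts fell, by construction, to 182, 788 and 714 (Δcra against WT on glucose, fructose, acetate), 613 and 842 (WT fructose and acetate against glucose), 177 and 711 (Δcra fructose and acetate against glucose), 259 (WT acetate against fructose), 726, 639 and 472 (interactions) and 408 (overall). With only the libraries compared, which leaves fewer libraries to estimate the spread, Δcra on glucose gave 767 and WT acetate against fructose 596. Array weights came out equal within each group. Replicate numbers did not pair the libraries (correlations -0.118 to 0.112), and as a block they gave 1165 on glucose. Among genes of 300 bases or longer never at 0, 1180 of 3049 passed on glucose, and voom called 1064 of 2802.

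With 1 library left out, counts ranged over 777 to 1308 (Δcra glucose), 1942 to 2278 (fructose), 1857 to 2218 (acetate), 1830 to 2107 (WT fructose), 2017 to 2302 (WT acetate), 524 to 840 and 1717 to 2080 (Δcra fructose and acetate against glucose) and 873 to 1190 (WT acetate against fructose). Each lowest count came without a library of the groups compared, which left fewer.

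Camera with an estimated correlation called 7, 8, 5, 3 and 7 lists in the 5 main contrasts, and fry, which asks whether a list moves at all, 25 on glucose, 22 on fructose, 26 on acetate, and 25 in both WT contrasts. The pyruvate dehydrogenase and fermentation list on acetate, not called by camera, which put it down, passed under fry as up (median -0.234, adjusted p = 0.000447), and epd on fructose came to log2 0.0089 (adjusted p = 0.88) with values as deposited; the cause was not tested. Lists not called that passed under another setting, fry aside, were nitrogen limitation, phosphate and the stable RNA and ribosomal lists in Δcra against WT, acid resistance and stable RNA in WT fructose, and stable RNA, methionine and genes beside cra in WT acetate. The r between genotype effects on glucose and fructose was 0.289 with a pseudocount of 0.1, 0.337 with at least 20 FPKM, 0.448 for the long genes and 0.449 with voom; for glucose and acetate 0.417 and 0.425 with the last pair, and for fructose and acetate 0.506 with a pseudocount of 0.1, 0.631 and 0.622. With 1 library left out these ranged over 0.264 to 0.323, 0.282 to 0.347 and 0.511 to 0.561. The cause was not tested.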

Other observations

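The genes of this part were chosen after their values were seen. On acetate, long genes in no list above moved too, given as Δcra against WT: aroF (an enzyme that opens aromatic synthesis, 9813 ± 122 vs 642 ± 2.53, 15.3-fold) rose, and sodB (b1656, iron superoxide dismutase, a known target of ryhB, 27.6 ± 0.321 vs 303 ± 36.1, 10.6-fold) and dppC (b3542, a dipeptide transporter subunit, 12.6 ± 2.19 vs 216 ± 5.35, 16.1-fold) fell. On fructose btsT (b4354, a pyruvate transporter, 197 ± 7.86 vs 6.59 ± 1.16, 26.3-fold) rose and tnaA (1.73 ± 0.0814 vs 81.0 ± 1.80, 30.1-fold) fell.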
